A study of Mus musculus with 9 samples.

How the data were processed

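Gene expression was measured in the liver of mice. Tumour-bearing mice were male BALB/c nu/nu mice, an athymic strain, aged 6 weeks when TK-4, a human colon cancer, was placed in the wall of the cecum, so that tumour and sampled organ were separate tissues. The strain, sex and age of the mice without tumour are not given separately in the sources used here. Treatment was TSU68 at 400 mg/kg per day by mouth or vehicle, from day 7 after implantation for 1 week. TSU68 is an oral inhibitor of receptor tyrosine kinases of the VEGF, PDGF and FGF receptor families. Arrays covered 3 groups of 3 samples: no tumour and vehicle (NT-Co), tumour and vehicle (T-Co) and tumour and TSU68 (T-TSU). Livers of treated mice without tumour are not analysed here. Samples were assigned to groups from their titles, and the replicate numbers are those of the titles. The labels give each sample a number but do not state that each comes from a separate animal, so p-values measure the spread between these samples. The hour of tissue collection and the feeding state are not given in the sources used here.

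Per the labels' protocols, total RNA was isolated with phenol-based and column purification, and biotin-labelled cRNA was made from 5 µg of it with a one-cycle synthesis kit for 3' expression arrays. The deposited values are linear array intensities, one per probe set and sample, and the summarisation and scaling software is not given in the sources used here. Every array had a mean of 500.3 after removal of 2% of values at each end, so the deposited intensities had been scaled to a common level. No detection calls were used. The table held 22690 probe sets, of which 64 were control probe sets and were left out of all tests. Among the other 22626, the platform annotation gave 1 gene for 20380, several genes for 691 and none for 1555. Of the 20380, 20351 were found in the RefSeq gene table by their gene identifier, and 0 symbols needed updating. Genes were named only from probe sets with 1 gene. The intensity table held no coordinates, so none are given.

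Intensities were analysed as log2(intensity + 7.92), the pseudocount being the 10th percentile of all values, so the fold changes understate those of dim genes. Array medians lay within 0.15 on the log2 scale, and no further normalization was applied. Probe sets whose mean was under the 30th percentile (an intensity of about 36.2) were left out, which removed 6788 and left 15838 probe sets of 9225 distinct genes. A group-means model was fitted to all 9 arrays with limma 3.58.1 in R 4.3.3, giving 6 residual degrees of freedom, with empirical Bayes moderation along the intensity trend. Tests were two-sided, with Benjamini-Hochberg adjustment over all probe sets tested and a threshold of 0.05. The comparisons were T-Co against NT-Co, T-TSU against T-Co, T-TSU against NT-Co, and a moderated F test of any difference between the 3 groups. Values are intensities as mean ± SD (n = 3), and log2 differences are given ± SE from the limma fit. The number of arrays limits the precision.

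In all, 37 gene lists of liver pathways and of cell types were written before the data were examined, and tested with limma's camera (preset correlation 0.01) on 1 probe set per gene, the brightest. The p-values were adjusted over the 37 lists within a comparison. Camera with an estimated correlation and fry were run beside it. Genes named in the text followed a rule fixed in advance. It took the 12 largest rises and the 12 largest falls among called probe sets whose groups did not overlap, with the brightest called probe set standing for each gene. It also took up to 4 members of each list that passed with the smallest p, 15 focus genes in every comparison, and up to 10 genes called in opposite directions for tumour and drug. Where fewer than 5 genes passed in a direction, those with the smallest unadjusted p filled up to 5. Members of a list outside this rule are named only as part of that list's count, and were chosen after their values were seen.

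T-Co arrays enter both the tumour and the drug difference, with opposite signs. The correlation and covariance with no effect were therefore simulated 100 times from the residuals of the fit. Values with a tumour effect but no drug effect were simulated 100 times with independent noise around the fitted group means. A slope of the drug difference on the tumour difference was computed after subtracting the variance and covariance that array noise gives. The pipeline was tested on simulated data over the 15838 probe sets. Unchanged probe sets called numbered 7.3, 6.7 and 8.0 on average for the 3 comparisons. For T-Co against NT-Co it recovered 44.0% of 2-fold and 76.3% of 4-fold changes. For T-TSU against T-Co it recovered 42.9% and 85.5%, and for T-TSU against NT-Co 43.9% and 83.7%. The simulated noise was independent between probe sets and equal in spread between groups, and the number of changed probe sets was fixed. Rates on the real arrays may therefore differ. The simulated slope came out at 0.0135 for a true value of 0 and at -0.492 for a true value of -0.5. Alternatives were another scaling (quantile or median), pseudocount, filter, variance model, array weights, 1 probe set per gene, 2 groups per fit, another threshold, and each array left out in turn. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.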

Results

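Liver RNA of mice with and without a colon cancer xenograft in the cecal wall was profiled on 9 mouse arrays. There were 3 samples each of mice without tumour on vehicle (NT-Co), tumour-bearing mice on vehicle (T-Co) and tumour-bearing mice given the kinase inhibitor TSU68 (T-TSU). Of 15838 probe sets tested, 902 differed between the groups by limma's F test. The count was 312 without the intensity trend and 354 to 1009 with 1 array left out. The median intensity of an array lay between 107 and 119. Within a group, the mean correlation of an array with the others was 0.947 to 0.964, and no arrays held duplicate values. The first principal component held 27.6% of the variance, and along it the NT-Co arrays lay at -40.3 to -34.5 and the T-Co arrays at 15.2 to 43.7. The T-TSU arrays lay at -3.4 to 19.5 and overlapped with T-Co. T-Co replicate 13 stood apart on the second component, at 48.1, where the other arrays lay between -29.9 and 17.5. The 3' to 5' intensity ratio of beta-actin, a measure of RNA integrity and labelling, was 2.72 ± 0.44 in NT-Co, 1.98 ± 0.11 in T-Co and 2.02 ± 0.20 in T-TSU (mean ± SD). That of Gapdh was 0.765 ± 0.031, 0.765 ± 0.039 and 0.767 ± 0.075.

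The comparison of T-Co with NT-Co asked how the liver differs between mice with a tumour in another organ and mice without. An operation on the mice without tumour is not described here, so the tumour and its implantation cannot be told apart. The fasting-responsive genes Igfbp1, which encodes an IGF-binding protein, and Lpin1, a phosphatidate phosphatase, rose by 4.94 ± 0.59 and 4.05 ± 0.47 on the log2 scale. These are 30.7-fold and 16.5-fold differences, with adjusted p = 0.000908 and 0.000902. Usp2, a deubiquitinase under clock control, rose by 3.97 ± 0.39, from an intensity of 76.8 ± 46.1 to 1160.3 ± 231. The metallothioneins Mt2 and Mt1, which bind zinc and copper, rose by 3.65 ± 0.59 and 3.45 ± 0.57. In the other direction, the steroid-metabolising enzyme Hsd3b5 fell by 5.24 ± 0.69, from 8716 ± 1410.0 to 296 ± 213, and the fatty acid elongase Elovl3 fell by 4.20 ± 0.40, from 13758 ± 2032 to 854 ± 473.

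Other large rises were those of Cyp17a1, a steroid hydroxylase (3.45 ± 0.49), the monooxygenase Fmo2 (3.40 ± 0.49), and St3gal5, the GM3 ganglioside synthase (3.29 ± 0.26). The p53-inducible Trp53inp1 (3.16 ± 0.37), the transcription factor Maff (2.88 ± 0.65), the G protein regulator Rgs16 (3.32 ± 0.85) and the clock output factor Dbp (3.17 ± 0.74) also rose. Large falls were those of G0s2, an inhibitor of the lipase ATGL (-3.53 ± 0.33), Tsc22d1 (-3.02 ± 0.39), and the DNA methyltransferase Dnmt3b (-2.99 ± 0.59). The tubulin gene Tubb2a (-2.84 ± 0.49), the organic anion transporter Slco1a1 (-2.74 ± 0.66) and Ppp1r3c, a glycogen-targeting phosphatase subunit (-2.71 ± 0.30), fell as well. So did the succinate receptor Sucnr1 (-2.59 ± 0.35), the lipid droplet protein Fitm1 (-2.56 ± 0.48), the feeding-induced hormone Angptl8 (-2.46 ± 0.55) and the acetyltransferase Nat8f5 (-2.40 ± 0.29). The sizes for Maff and Dnmt3b are uncertain, since Maff in NT-Co (15.7 ± 16.0) and Dnmt3b in T-Co (17.5 ± 8.67) lay near background.

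Genes of gluconeogenesis and fasting rose as a list (camera adjusted p = 6.24e-08; adjusted p = 0.407 with an estimated correlation), with a mean of 1.21 on the log2 scale. Of this list, 12 of 26 measured members rose and 0 fell (17 and 0 adjusted over the list alone). Beside Igfbp1, these included the transcription factor Cebpb (2.20 ± 0.29), the aspartate aminotransferase Got1 (1.70 ± 0.25) and Pck1, which catalyses the committed step of gluconeogenesis (0.91 ± 0.15). The beta-actin ratio differed between the same groups, as given above. The feeding state and hour of collection are not given, so a difference in either cannot be told apart from an effect of the tumour.

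Circadian clock genes shifted in both directions. Of this list, 8 of 17 measured members rose and 1 fell (10 and 1 adjusted over the list alone), with a camera adjusted p of 9.61e-06 for a rise (adjusted p = 0.121 with an estimated correlation). Usp2, Tef (1.71 ± 0.18), the nuclear receptor Nr1d2 (1.76 ± 0.21) and the period genes Per1 (2.10 ± 0.40) and Per3 (2.14 ± 0.46) rose. Arntl, the activator of the clock loop, fell by 2.16 ± 0.53 (adjusted p = 0.0320). It passed without T-Co replicate 13, and not without any other array of the 2 groups (adjusted p from 0.0863 to 0.101). Per3 did not pass without NT-Co replicate 11 (0.0535) or T-Co replicate 10 (0.0573), and with an NT-Co intensity of 26.9 ± 18.4, near background, the size of its rise is uncertain. The mean of 10 genes of the Dbp and Per side of the cycle was 1.78 ± 0.55 (SD) above NT-Co in the T-Co arrays. The mean of Arntl, Clock and Nfil3 lay at -1.48 and -1.45 in T-Co replicates 9 and 10, and at 0.00 in replicate 13. The beta-actin ratio also differed between T-Co and NT-Co.

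Acute phase genes, which the liver expresses in inflammation, rose as a list by a mean of 0.89 (camera adjusted p = 2.57e-12; adjusted p = 0.407 with an estimated correlation). Of this list, 16 of 40 measured members rose and 0 fell (27 and 0 adjusted over the list alone), and 39 of the 40 had a difference above 0. As written, it also held Alb, Ttr and Apoa1, which the hepatocyte list shares and which the liver lowers, not raises, in inflammation. A rise of every member is therefore not a sign of inflammation by itself. Stat3, the transducer of interleukin-6 signalling, rose by 1.28 ± 0.15, the zinc transporter Slc39a14 by 1.06 ± 0.13 and the hepatokine Fgl1 by 1.11 ± 0.16. Cebpb, given above with the fasting genes, belongs to the acute phase list too, so its call counts in both. The best-known markers did not pass adjustment over all probe sets. Saa1 differed by 1.15 ± 0.32 (adjusted p = 0.0520), Saa2 by 2.45 ± 0.73 (0.0659) and Lcn2 by 2.08 ± 0.58 (0.0521). Per array, the list mean in T-Co was 0.59 to 1.25 above NT-Co, the highest value being that of replicate 13. The beta-actin ratio was lower in T-Co than in NT-Co as well, as given above. Saa1 and Saa2, and Mt1 and Mt2, are close paralogs whose probe sets can share signal.

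The chemokine Cxcl1, which attracts neutrophils, had an intensity of 814 ± 865 in NT-Co and 2833 ± 1740.3 in T-Co, and the difference of 2.05 ± 0.67 did not pass (adjusted p = 0.0916). The neutrophil genes S100a8 (1.59 ± 0.45, adjusted p = 0.0563) and S100a9 (1.23 ± 0.38, 0.0728) did not pass either. By limma, none of 13 measured neutrophil markers was called (2 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.194). Macrophage and Kupffer cell markers rose as a list (camera adjusted p = 0.00709; adjusted p = 0.736 with an estimated correlation), with 1 of 19 called, the haemoglobin scavenger Cd163 (1.47 ± 0.36). C1qa (1.09 ± 0.35), C1qb (0.91 ± 0.36) and Ctss (0.47 ± 0.22) did not pass, and 1 of the other 2 probe sets of C1qb had the opposite sign. Endothelial markers rose as a list (camera adjusted p = 0.00227; adjusted p = 0.736 with an estimated correlation), with 2 of 28 called, Bmp2 (1.22 ± 0.22) and Pecam1 (1.89 ± 0.50, from 34.6 ± 29.6, near background, so of uncertain size). Lyve1 (1.52 ± 0.48) and Nrp1 (-0.38 ± 0.14) did not pass. Both list calls were lost without T-Co replicate 13 (camera adjusted p = 0.0590 for macrophage and 0.0912 for endothelial markers), and the macrophage call also without NT-Co replicate 8 (0.0670). These lists likewise moved between groups that differed in the beta-actin ratio.

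Liver genes expressed more in males than in females fell as a list (mean -1.43, camera adjusted p = 4.82e-09; adjusted p = 0.407 with an estimated correlation). Of this list, 0 of 19 measured members rose and 6 fell (0 and 16 adjusted over the list alone). All 19 differences were below 0. Hsd3b5 and Elovl3 led the list, followed by the adipokine Serpina12 (-1.70 ± 0.26) and the peroxisomal hydrolase Nudt7 (-1.63 ± 0.29). Female-biased liver genes rose as a list (mean 1.53, camera adjusted p = 9.51e-09; adjusted p = 0.121 with an estimated correlation). Of this list, 8 of 15 measured members rose and 0 fell (10 and 0 adjusted over the list alone). Beside Cyp17a1 and Fmo2, these included the transcriptional cofactor Trim24 (1.94 ± 0.19) and the transporter Slco1a4 (1.59 ± 0.24). For both sex-biased lists, too, the beta-actin ratio differed between T-Co and NT-Co.

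Immediate early genes rose as a list (camera adjusted p = 0.000259; adjusted p = 0.420 with an estimated correlation), with 5 of 24 called, among them Junb (2.25 ± 0.46), Btg2 (1.96 ± 0.43), Dusp1 (1.76 ± 0.37) and Zfp36 (1.28 ± 0.24). Adjusted over the list alone, 7 rose and 1 fell. Iron, haem and metal genes rose (camera adjusted p = 0.00334; adjusted p = 0.407 with an estimated correlation), and the 4 of 22 members called were Mt1, Mt2, Slc39a14 and the metalloreductase Steap4 (0.86 ± 0.21). All 4 also belong to the acute phase list, so these calls are not a separate result. Adjusted over the iron list alone, 7 rose and 1 fell. Hepatocyte markers rose by a small mean of 0.25 (camera adjusted p = 0.00124; adjusted p = 0.420 with an estimated correlation). The 4 of 17 called (5 adjusted over the list alone) were Cps1 (0.46 ± 0.09) and Arg1 (0.47 ± 0.09) of the urea cycle, the plasma protein Ahsg (0.51 ± 0.10) and the tyrosine aminotransferase Tat (0.86 ± 0.20). Without the intensity trend none of these 4 passed (adjusted p = 0.0882 for Cps1, 0.0834 for Arg1, 0.0911 for Ahsg and 0.0957 for Tat). Cps1 did not pass without the filter (0.0529) or with centred arrays (0.0506) either, and Ahsg without the filter (0.0518). After quantile normalization this list had a mean of 0.14 and did not pass (adjusted p = 0.0621). NRF2 and oxidative stress targets fell (camera adjusted p = 0.0222; adjusted p = 0.420 with an estimated correlation). Of these, 1 of 23 measured members rose and 6 fell (3 and 11 adjusted over the list alone). The glutathione transferases Gstm3 (-1.81 ± 0.26) and Gstm2 (-1.04 ± 0.20) and Gclc, of glutathione synthesis (-1.16 ± 0.18), fell, while the transporter Abcc3 rose (1.16 ± 0.19). Beside these 4 lists, too, the beta-actin ratio was lower in T-Co than in NT-Co.

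Genes of the pathways that TSU68 acts on were not called in T-Co against NT-Co. The differences were -0.28 ± 0.23 for Vegfa, 0.11 ± 0.22 for the VEGF receptor Kdr, 1.21 ± 0.46 for Flt1, -1.20 ± 0.37 for Pdgfrb (adjusted p = 0.0750) and 0.55 ± 0.54 for Fgfr1. The other 2 probe sets of Flt1 had the opposite sign. Mmp9 lay below the intensity filter and was not tested. The drug-metabolising genes Cyp1a1 (0.00 ± 0.29), Cyp1a2 (-0.37 ± 0.14) and Cyp2b10 (1.05 ± 0.57) were not called.

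In total 1036 probe sets were called between T-Co and NT-Co, 659 higher (501 genes) and 377 lower (302 genes), and 520 differed at least 2-fold. The arrays of the 2 groups did not overlap for 1035 of them. Over all probe sets they did not overlap for 26.9%, where chance gives 10%. With an estimated correlation 0 of the 37 lists passed (4 at an unadjusted p under 0.05), and by fry 7 passed. The count was 467 without NT-Co replicate 8 and 440 without NT-Co replicate 11. Of 56 calls named by the rule, 15 were lost without 1 array or another. The highest adjusted p arose without NT-Co replicate 11 for Rgs16 (0.145), Dbp (0.0823), Slco1a1 (0.0901), Angptl8 (0.0718), Pecam1 (0.143), Gstm2 (0.0515), Btg2 (0.0825) and Ces1d (0.127), without NT-Co replicate 8 for Dnmt3b (0.0632), Cd163 (0.112), Ahsg (0.0613), Tat (0.0748), Dusp1 (0.0606) and Steap4 (0.111), and without T-Co replicate 10 for Maff (0.0771). Without the intensity trend 17 were lost, the 4 hepatocyte genes given above and Rgs16 (0.110), Dbp (0.0896), Maff (0.0606), Slco1a1 (0.0947), Angptl8 (0.0777), Cd163 (0.0925), Pecam1 (0.0745), Gstm2 (0.0550), Junb (0.0595), Dusp1 (0.0696), Btg2 (0.0706), Steap4 (0.0963) and Ces1d (0.101). The call also ended with a robust trend for Rgs16, Dbp (0.126), Slco1a1 (0.132) and Angptl8 (0.0850), without the filter for Pecam1 (0.0632), and with only these 2 groups for Pecam1 (0.0589) and Ces1d (0.0503).

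**Figure D1:**
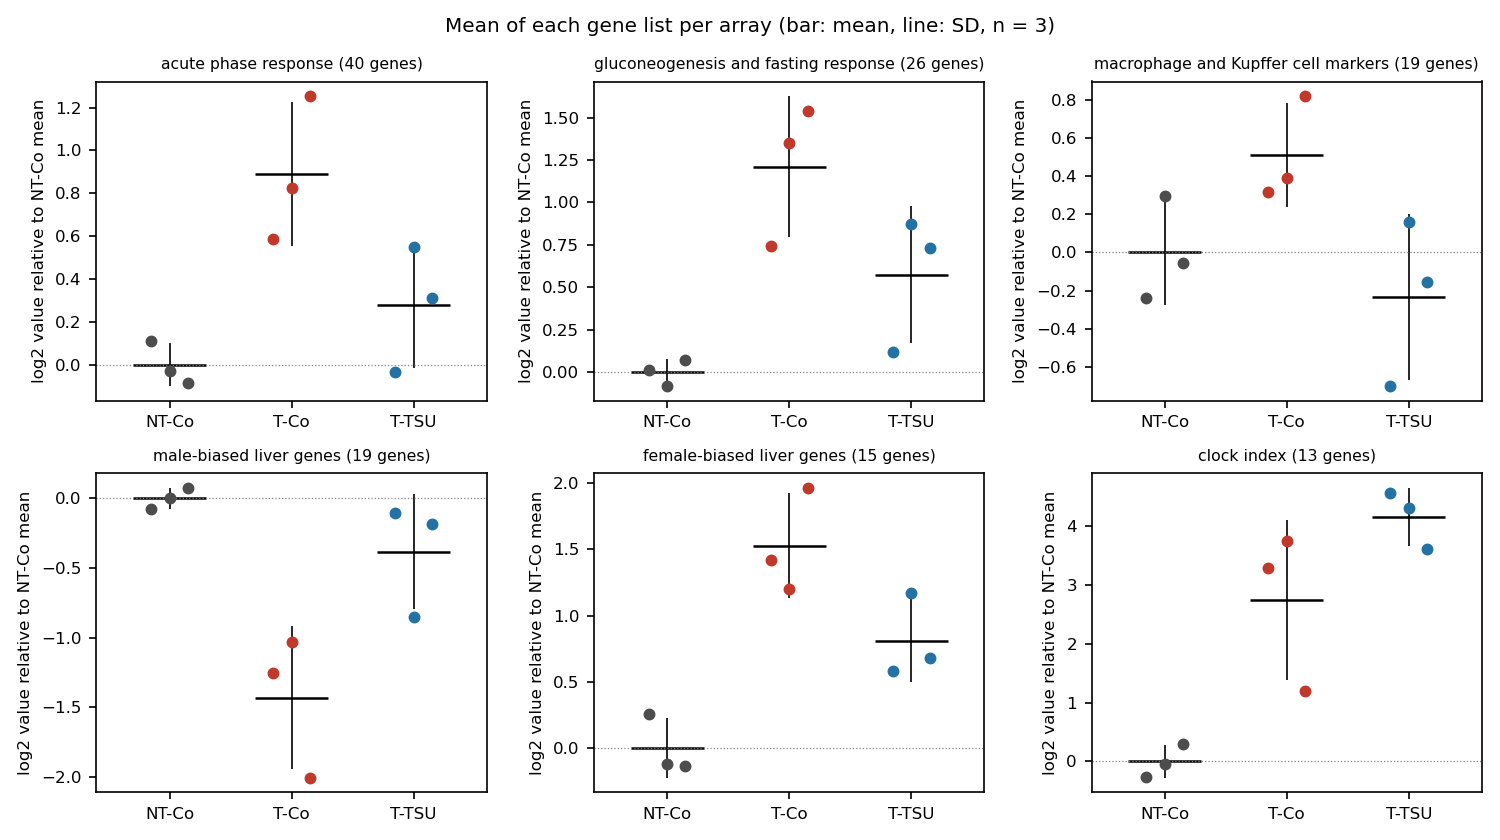
Mean log2 value of 6 gene groups on each array, relative to the NT-Co mean, with points for arrays, horizontal bars for group means and vertical lines for SD (n = 3 per group). The clock index is the mean of 10 clock genes of the Dbp and Per side minus that of Arntl, Clock and Nfil3. T-Co arrays lay at 0.59 to 1.25 for acute phase genes and T-TSU arrays at -0.03 to 0.55.

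The comparison of T-TSU with T-Co asked how TSU68 changed the liver of tumour-bearing mice. Only 8 probe sets were called, all at an adjusted p of 0.0453, and 6 of them rose. The carboxylesterase Ces1d rose by 0.94 ± 0.14 (2 probe sets, the other by 1.06 ± 0.13), from an intensity of 3921 ± 514 to 7492 ± 672. The hydroxysteroid dehydrogenase Hsd3b2 rose by 1.36 ± 0.19, from 331 ± 67.2 to 853 ± 47.6, and the acetyltransferase Nat8f5 by 1.91 ± 0.29, from 164 ± 38.6 to 669.7 ± 265. Marveld1 (1.16 ± 0.17) and the glyoxalase Hagh (0.95 ± 0.14) also rose. Sco2, a copper chaperone of cytochrome c oxidase, fell by 0.86 ± 0.12, from 1822 ± 79.6 to 1000.4 ± 52.9, and 1 probe set with no gene in the annotation fell by 0.69 ± 0.10. Hsd3b2, Ces1d and Nat8f5 belong to families of close paralogs whose probe sets can share signal.

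Several differences lay just past the threshold and were not called. Ctsl (-0.65 ± 0.11), a lysosomal protease, Plpp1 (-1.62 ± 0.27), the amylase gene Amy1 (-0.68 ± 0.11) and Acnat2 (-2.21 ± 0.38) were the falls with the smallest p after the called ones, each at an adjusted p of 0.0593. Hsd3b5 had an intensity of 296 ± 213 in T-Co and 4767 ± 3439 in T-TSU, a difference of 4.01 ± 0.69 (adjusted p = 0.0593). Cyp17a1 had 1508 ± 996 and 219 ± 156, a difference of -2.75 ± 0.49 (0.0651).

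The inflammatory focus genes had lower means in T-TSU than in T-Co, and none passed. Cxcl1 had an intensity of 569 ± 242 in T-TSU against 2833 ± 1740.3 in T-Co, a difference of -2.13 ± 0.67 (adjusted p = 0.304). The differences were -1.73 ± 0.45 for S100a8 (0.201), -1.46 ± 0.38 for S100a9 (0.201), -0.96 ± 0.32 for Saa1 (0.324), -1.35 ± 0.73 for Saa2 (0.557) and -1.65 ± 0.58 for Lcn2 (0.342). Vegfa (0.40 ± 0.23), Kdr (-0.37 ± 0.22), Flt1 (-1.43 ± 0.46), Pdgfrb (0.50 ± 0.37) and Fgfr1 (-0.39 ± 0.54) were not called. Cyp1a1 (-0.17 ± 0.29), Cyp1a2 (0.53 ± 0.14, adjusted p = 0.201) and Cyp2b10 (-1.18 ± 0.57) were not called either.

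**Figure D2:**
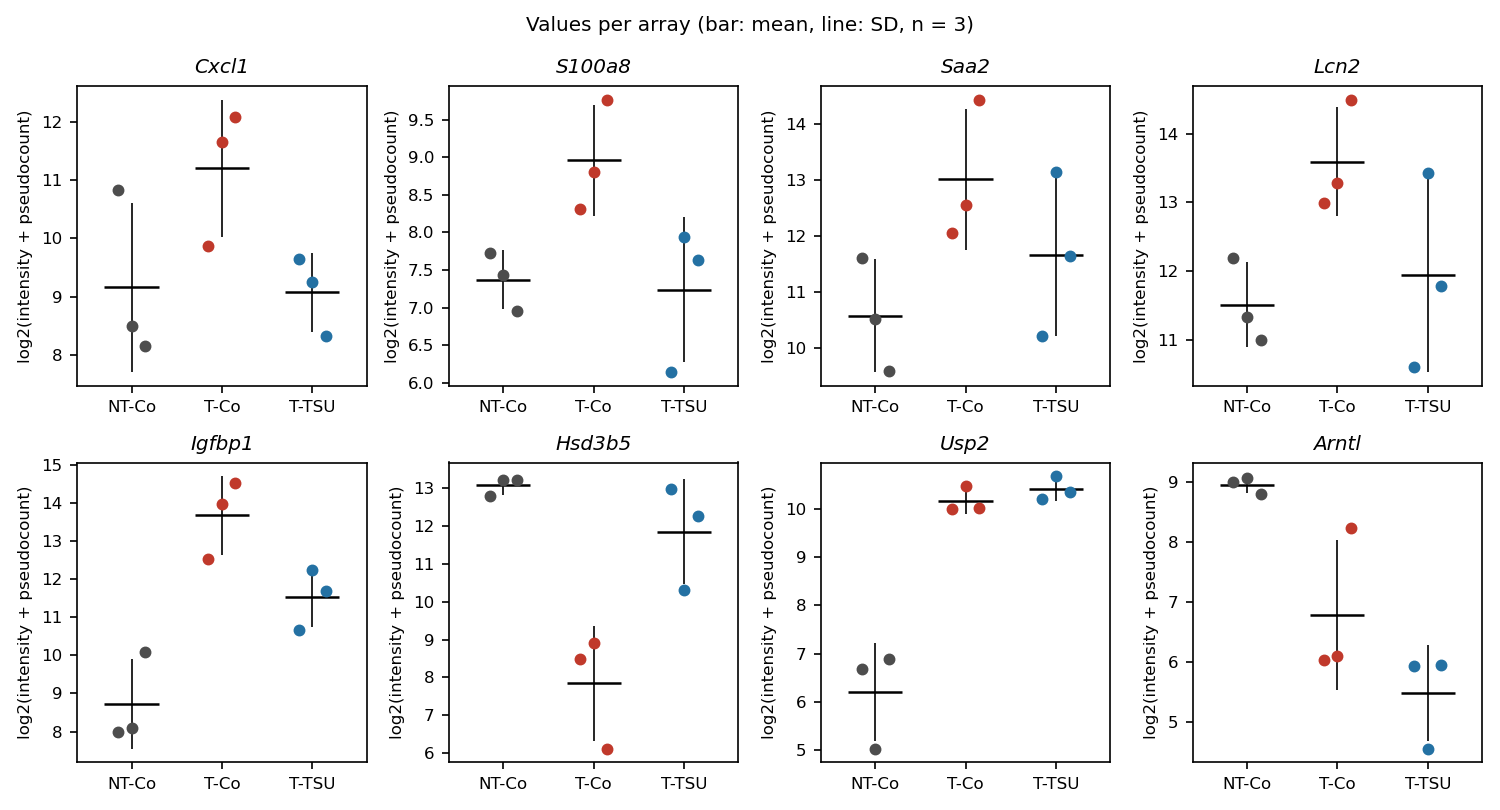
Values of 8 genes on each array as log2(intensity + pseudocount), with points for arrays, horizontal bars for group means and vertical lines for SD (n = 3 per group). Hsd3b5 was lowest in T-Co, where its mean intensity was 296 against 8716 in NT-Co, and Usp2 was higher in both tumour groups than in NT-Co.

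As lists, 19 of 37 passed camera for T-TSU against T-Co, 14 lower and 5 higher, while 0 of their members, by the brightest probe set of each gene, were called by limma over all probe sets. Acute phase genes fell by a mean of 0.61 (camera adjusted p = 1.85e-13; adjusted p = 0.385 with an estimated correlation), with 24 of 40 lower adjusted over the list alone. Examples, none called over all probe sets, were Serpina3n (-0.93 ± 0.17), the iron hormone Hamp (-0.77 ± 0.17), Lbp (-1.06 ± 0.25) and Fgl1 (-0.69 ± 0.16). Male-biased genes rose by a mean of 1.05 (camera adjusted p = 8.20e-09; adjusted p = 0.385 with an estimated correlation), with 9 of 19 higher adjusted over the list alone, among them Serpina12 (1.52 ± 0.26), Keg1 (1.33 ± 0.29) and C6 (0.91 ± 0.23). Female-biased genes fell (-0.72, camera adjusted p = 0.00268; adjusted p = 0.385 with an estimated correlation), with 5 of 15 lower and 1 higher adjusted over the list alone. The list did not pass with a filter at the 50th percentile (adjusted p = 0.0535). Cyp39a1 differed by -1.60 ± 0.46, Slco1a4 by -0.93 ± 0.24 and Trim24 by -0.57 ± 0.19.

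Macrophage and Kupffer cell markers fell by a mean of 0.74 (camera adjusted p = 1.86e-08; adjusted p = 0.385 with an estimated correlation), and 9 of 19 were lower adjusted over the list alone. C1qa differed by -1.45 ± 0.35, Vsig4 by -1.09 ± 0.32, Cd5l by -0.71 ± 0.22 and Mrc1 by -1.04 ± 0.34. Neutrophil markers fell (-0.45, camera adjusted p = 0.0189; adjusted p = 0.385 with an estimated correlation), with 3 of 13 lower adjusted over the list alone; Lyz2 differed by -0.80 ± 0.26 and Fpr2 by -0.79 ± 0.36. Without T-Co replicate 13 the neutrophil list had a mean of -0.23 and did not pass (adjusted p = 0.129), nor did it without T-TSU replicate 2 (0.0727) or 14 (0.0564). Chemokines and cytokines fell (-0.43, camera adjusted p = 0.0463; adjusted p = 0.385 with an estimated correlation), with 1 of 16 lower adjusted over the list alone. Ccl6 differed by -1.48 ± 0.36, Ccl24 by -1.37 ± 0.50 and Cxcl12 by -0.34 ± 0.12, and another probe set of Cxcl12 had the opposite sign. The chemokine list did not pass without a pseudocount (adjusted p = 0.0534), with the 25th percentile as pseudocount (0.143) or without the filter (0.347). With 1 array left out it passed only without T-Co replicate 9 or T-TSU replicate 12 (0.0583 to 0.317 without the others). Endothelial markers fell (-0.31, camera adjusted p = 0.00246; adjusted p = 0.509 with an estimated correlation), with 0 of 28 past adjustment over the list alone, as in Clec4g (-0.66 ± 0.21), whereas Nrp1 differed by 0.43 ± 0.14. Without T-Co replicate 13 the endothelial list had a mean of -0.15 (adjusted p = 0.139), and without T-TSU replicate 2 one of -0.14 (0.163), and it passed in neither case. Stellate cell and fibroblast markers rose (0.18, camera adjusted p = 0.0116; adjusted p = 0.385 with an estimated correlation), with 1 of 20 higher adjusted over the list alone. Lum differed by 0.67 ± 0.16, Col3a1 by 0.61 ± 0.20, Reln by 0.38 ± 0.15 and Rgs5 by 0.34 ± 0.14. The stellate list did not pass without T-TSU replicate 14 (mean 0.13, adjusted p = 0.110). Relative to NT-Co, its mean was -0.13 ± 0.07 (SD) in T-Co and 0.04 ± 0.11 in T-TSU, so the rise was toward the NT-Co level. Col3a1 and Sparc, whose falls in T-Co are given with the extracellular matrix genes below, belong to this list too.

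Among metabolic lists, PPAR alpha targets rose by a mean of 0.30 (camera adjusted p = 0.000165; adjusted p = 0.385 with an estimated correlation), with 2 of 34 higher adjusted over the list alone. Relative to NT-Co, the list mean was -0.35 to 0.23 in T-Co arrays and 0.24 to 0.44 in T-TSU arrays. The T-Co mean was 0.01, so 1 low T-Co array enlarged the difference. Acaa1a differed by 1.07 ± 0.22, Acot1 by 1.98 ± 0.52, Ehhadh by 0.89 ± 0.29 and Decr1 by 0.51 ± 0.16. Fasting genes fell (-0.64, camera adjusted p = 0.000243; adjusted p = 0.385 with an estimated correlation), with 4 of 26 lower adjusted over the list alone, as in Got1 (-1.24 ± 0.25), Nnmt (-1.66 ± 0.44), Igfbp1 (-2.14 ± 0.59) and Ddit4 (-2.38 ± 0.72). The fasting list mean was 0.74 to 1.54 above NT-Co in T-Co arrays and 0.12 to 0.87 in T-TSU arrays, so the groups overlapped. Cholesterol synthesis genes fell (-0.73, camera adjusted p = 0.000680; adjusted p = 0.521 with an estimated correlation), with 1 of 20 lower adjusted over the list alone, as in Mvd (-1.43 ± 0.34), Cyp51 (-1.71 ± 0.60) and Nsdhl (-1.31 ± 0.47). Without T-Co replicate 13 the mean of that list was only -0.06. Its test then turned to the other direction, with a camera adjusted p of 0.999. Urea cycle and amino acid genes fell (-0.16, camera adjusted p = 0.00672; adjusted p = 0.385 with an estimated correlation), with 6 of 34 lower adjusted over the list alone, as in Asl (-0.72 ± 0.17), Cth (-0.55 ± 0.12) and Cbs (-0.50 ± 0.12). Without T-Co replicate 10 the urea cycle list did not pass (adjusted p = 0.0713). NRF2 targets rose (0.23, camera adjusted p = 0.0285; adjusted p = 0.385 with an estimated correlation), with 3 of 23 higher and 1 lower adjusted over the list alone. Gstm3 (1.09 ± 0.26), Gstm2 (0.71 ± 0.20) and Gsta4 (0.76 ± 0.21) lay above 0 and Sqstm1 (-0.43 ± 0.11) below. The NRF2 list did not pass without T-Co replicate 10 (adjusted p = 0.0527) or without T-TSU replicate 2 (0.133) or 12 (0.0733).

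Hepatocyte markers fell by a mean of 0.23 (camera adjusted p = 3.01e-05; adjusted p = 0.385 with an estimated correlation), with 3 of 17 lower adjusted over the list alone, as in Ahsg (-0.44 ± 0.10), Bhmt (-0.31 ± 0.09) and Gnmt (-0.34 ± 0.12). After quantile normalization the mean of the hepatocyte list was -0.07 and it did not pass (adjusted p = 0.224). Immediate early genes fell (-0.48, camera adjusted p = 0.000165; adjusted p = 0.385 with an estimated correlation), with 0 of 24 past adjustment over the list alone, as in Egr1 (-1.74 ± 0.50), Jund (-0.76 ± 0.24), Junb (-1.39 ± 0.46) and Klf4 (-1.53 ± 0.52). Relative to NT-Co, the immediate early list mean was 0.27 to 1.12 in T-Co arrays and 0.11 to 0.43 in T-TSU arrays, so the groups overlapped. Heat shock and unfolded protein genes fell (-0.26, camera adjusted p = 0.00120; adjusted p = 0.462 with an estimated correlation), with 0 of 33 past adjustment over the list alone, as in Hspa5 (-0.63 ± 0.20), Calr (-0.30 ± 0.10), Atf3 (-0.89 ± 0.35) and Pdia4 (-0.39 ± 0.16). The heat shock list did not pass without T-Co replicate 9 (mean -0.15, adjusted p = 0.0862). Iron, haem and metal genes fell (-0.32, camera adjusted p = 0.00672; adjusted p = 0.385 with an estimated correlation), with 2 of 22 lower adjusted over the list alone, as in Cp (-0.48 ± 0.12) and Slc39a14 (-0.42 ± 0.13), both also in the acute phase list. Without T-TSU replicate 2 the iron list had a mean of -0.18 and did not pass (adjusted p = 0.0586). Complement and coagulation genes passed as lower (median -0.11, camera adjusted p = 0.0333; adjusted p = 0.398 with an estimated correlation), with 8 of 36 lower and 3 higher adjusted over the list alone. Fgg (-0.32 ± 0.08) and Fgb (-0.38 ± 0.10) lay below 0, and C6 and F11 (0.63 ± 0.16) above. The complement list did not pass after quantile normalization (adjusted p = 0.265) or with centred arrays (0.0584). Nor did it without NT-Co replicate 11 (0.0511), T-Co replicate 10 (0.0527) or 13 (0.121), or T-TSU replicate 2 (0.0539) or 12 (0.341). The 6 measured pancreatic and intestinal markers passed as higher (0.43, camera adjusted p = 0.0485; adjusted p = 0.385 with an estimated correlation), with 2 higher adjusted over the list alone. Fabp2 differed by 1.25 ± 0.30, Lgals4 by 0.28 ± 0.24 and Prss2 by -0.65 ± 0.54. Without the filter the mean of these markers was -0.01 (adjusted p = 0.743), and they did not pass after quantile normalization (0.0619), with centred arrays (0.0585) or without a pseudocount (0.0534) either. With 1 array left out they passed only without NT-Co replicate 11 (0.0554 to 0.167 without the others).

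For T-TSU against T-Co, 1658 probe sets (10.5%) had an unadjusted p under 0.05, and the arrays of the 2 groups did not overlap for 14.1% of all probe sets, where chance gives 10%. With an estimated correlation 0 lists passed (1 at an unadjusted p under 0.05), and by fry 0 passed (10 unadjusted). Array means of T-Co and T-TSU overlapped for the fasting and immediate early lists, as given above. They also overlapped for the neutrophil, chemokine, endothelial, stellate cell and cholesterol lists. The same held for the NRF2, heat shock, iron and complement lists. The count of 8 fell to 0 without NT-Co replicate 8 or 11 or without T-TSU replicate 2 or 14, was 3 without T-Co replicate 13, and rose to 32 without T-Co replicate 10 and 59 without T-TSU replicate 12. It was 0 after centring each array on its median and 1 after quantile normalization.

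Compared with mice without tumour, treated tumour-bearing mice still differed, and here tumour and drug both differ. The clock output gene Dbp rose by 4.62 ± 0.74, from an intensity of 82.2 ± 14.7 to 2487 ± 1609.7, and by 5.13 on a dimmer probe set. Usp2 rose by 4.22 ± 0.39 and the period gene Per3 was called higher. Arntl fell from 491 ± 48.9 to 41.0 ± 21.9, near background, so the size of its fall cannot be judged, and the same holds for the rise of Per3, at 26.9 ± 18.4 in NT-Co. Elovl3 fell by 3.49 ± 0.40, from 13758 ± 2032 to 1250.5 ± 376, and the tubulin gene Tubb2a fell by 3.62 ± 0.49.

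Other large rises were those of Lpin1 (3.65 ± 0.47), the uridine phosphorylase Upp2 (3.45 ± 0.34), Rgs16 (3.43 ± 0.85), Fmo2 (3.28 ± 0.49), Clec2d (3.11 ± 0.31), St3gal5 (2.89 ± 0.26), Igfbp1 (2.80 ± 0.59) and the cell cycle kinase Wee1 (2.80 ± 0.34). The metabolic coactivator Ppargc1a was called higher on 1 probe set, whose NT-Co intensity (9.61 ± 4.81) lay near background, so the size of the rise cannot be judged, and its other 4 had the same sign without passing. Large falls included the tight junction gene Cldn1 (-2.56 ± 0.40), Angptl8 (-2.53 ± 0.55), Dnmt3b (-2.43 ± 0.59), the choline kinase Chka (-2.42 ± 0.29), Spon2 (-2.38 ± 0.48), the mitochondrial protease subunit Clpx (-2.37 ± 0.24), Celsr1 (-2.24 ± 0.48), Ppp1r3c (-2.18 ± 0.30) and the oxygen sensor Egln3 (-2.15 ± 0.49). Dnmt3b (35.1 ± 26.0), Spon2 (28.5 ± 17.1) and Egln3 (27.8 ± 29.7) lay near background in T-TSU, so the sizes of their falls are uncertain.

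Clock genes rose as a list (camera adjusted p = 5.42e-08; adjusted p = 0.0555 with an estimated correlation). Of these, 11 of 17 measured members rose and 2 fell (12 and 2 adjusted over the list alone). Tef (2.01 ± 0.18) and Nr1d2 (2.14 ± 0.21) were among the rises, and Clock (-1.50 ± 0.29) fell with Arntl. Clock did not pass without NT-Co replicate 8 (adjusted p = 0.0622) or 11 (0.0512). Female-biased genes rose (camera adjusted p = 3.19e-05; adjusted p = 0.359 with an estimated correlation). Of these, 3 of 15 measured members rose and 0 fell (6 and 0 adjusted over the list alone), and Trim24 (1.38 ± 0.19) and the thioesterase Acot3 (2.17 ± 0.33) were among them, while Tox (1.08 ± 0.31) did not pass. Fasting genes rose (camera adjusted p = 0.00101; adjusted p = 0.986 with an estimated correlation). Of these, 6 of 26 measured members rose and 0 fell (9 and 2 adjusted over the list alone). Among the rises were Cebpb (1.71 ± 0.29), which the acute phase list shares, Gpt2 (0.83 ± 0.15) and Pck1 (0.72 ± 0.15). PPAR alpha targets rose (camera adjusted p = 0.00809; adjusted p = 0.986 with an estimated correlation). Of these, 4 of 34 measured members rose and 1 fell (8 and 2 adjusted over the list alone). Cpt1a, of mitochondrial fatty acid uptake (1.07 ± 0.22), and Eci2 (0.62 ± 0.15) rose, and the lipid droplet gene Plin2 (-0.91 ± 0.14) fell. Acot3, named above with the female-biased genes, is a member of the PPAR alpha list too, so its call counts in both. Heat shock and unfolded protein genes fell (camera adjusted p = 0.0145; adjusted p = 0.986 with an estimated correlation), with 1 of 33 called lower, the chaperone Calr (-0.58 ± 0.10), and 9 lower and 1 higher adjusted over the list alone. Hspe1 (-0.40 ± 0.11), Hsp90b1 (-0.53 ± 0.15) and Chac1 (1.64 ± 0.42) did not pass. That list did not pass without NT-Co replicate 10 (adjusted p = 0.484) or T-TSU replicate 2 (0.0833). The beta-actin ratio was lower in T-TSU than in NT-Co, as given above.

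The acute phase and male-biased lists did not pass in T-TSU against NT-Co (camera adjusted p = 0.148 and 0.148). Of acute phase genes, 4 of 40 measured members rose and 0 fell (8 and 0 adjusted over the list alone), and of male-biased genes, 0 of 19 measured members rose and 1 fell (0 and 1 adjusted over the list alone). Cxcl1 (-0.09 ± 0.67), S100a8 (-0.14 ± 0.45), S100a9 (-0.23 ± 0.38), Saa1 (0.19 ± 0.32), Saa2 (1.10 ± 0.73) and Lcn2 (0.43 ± 0.58) were not called. Vegfa (0.12 ± 0.23), Kdr (-0.25 ± 0.22), Flt1 (-0.22 ± 0.46), Pdgfrb (-0.70 ± 0.37), Fgfr1 (0.17 ± 0.54), Cyp1a1 (-0.16 ± 0.29), Cyp1a2 (0.16 ± 0.14) and Cyp2b10 (-0.12 ± 0.57) were not called either. Of the list of VEGF, PDGF, FGF and angiopoietin ligands and receptors, 1 of 28 measured members rose and 0 fell (1 and 0 adjusted over the list alone). The call was that of Met, a receptor tyrosine kinase (0.84 ± 0.17), and it was lost without NT-Co replicate 8 (adjusted p = 0.0559) or 11 (0.0917) or T-TSU replicate 14 (0.0915). In total 609 probe sets were called, 394 higher (295 genes) and 215 lower (164 genes), all without overlap between the groups (24.2% over all probe sets, where chance gives 10%). The count was 324 and 297 without NT-Co replicates 8 and 11, and 323 and 287 without T-TSU replicates 12 and 14. Of 35 calls that the rule named here, 10 were lost in that way. The highest adjusted p arose without NT-Co replicate 11 for Rgs16 (0.165), Dnmt3b (0.163) and Eci2 (0.154), without NT-Co replicate 8 for Spon2 (0.0680) and Egln3 (0.107), without T-TSU replicate 12 for Igfbp1 (0.0967), and without T-TSU replicate 14 for Angptl8 (0.0873), Pck1 (0.0945), Celsr1 (0.0979) and Cpt1a (0.0879). Without the intensity trend 11 were lost, Igfbp1 (0.0929), Rgs16 (0.134), Dnmt3b (0.0770), Angptl8 (0.0952), Pck1 (0.103), Calr (0.0732), Celsr1 (0.0862), Egln3 (0.0599), Cpt1a (0.0876), Eci2 (0.130) and Gpt2 (0.0649). The call also ended with a robust trend for Igfbp1 (0.131), Rgs16 (0.185), Dbp (0.0603) and Angptl8 (0.107), with the 25th percentile as pseudocount for Rgs16 (0.0563), without the filter for Rgs16 (0.0576) and Dnmt3b (0.0512), and without a pseudocount for Dnmt3b (0.0818). With an estimated correlation 0 lists passed (2 at an unadjusted p under 0.05), and by fry 2 passed.

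The last comparison asked whether what moved with the tumour moved back with TSU68. Genes called lower in T-Co and higher in T-TSU were Nat8f5 (-2.40 and 1.91), Hsd3b2 (-1.39 and 1.36), Hagh (-0.88 and 0.95) and Ces1d (-0.57 and 0.94). In T-TSU, Hsd3b2 (-0.03 ± 0.19), Hagh (0.07 ± 0.14), Ces1d (0.36 ± 0.14) and Nat8f5 (-0.49 ± 0.29) were not called against NT-Co. These were 5 probe sets, and 1 more, the probe set with no gene, was called higher in T-Co and lower in T-TSU. Sco2 was called lower in both steps (-0.51 and -0.86). The first of these calls was lost without NT-Co replicate 8 (adjusted p = 0.117) or 11 (0.138) or T-Co replicate 10 (0.0664) or 13 (0.0577), and the second without any array but NT-Co replicate 10, T-Co replicate 10 or T-TSU replicate 12 (0.0652 to 0.200). Independent lists of these sizes would share 0.143 and 0.0832 probe sets of opposite direction. Simulations with a tumour effect but no drug effect gave at most 1, with noise drawn independently for each probe set. Part of the excess may come from the shared T-Co arrays, which number too few to split.

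Of the 1036 probe sets called between T-Co and NT-Co, 413 (39.9%) were also called in T-TSU against NT-Co in the same direction, 299 higher and 114 lower. Independent lists would share 16.4 and 5.12. The share moved most without T-TSU replicate 12 (231 of 983), T-TSU replicate 14 (221 of 872) or T-Co replicate 13 (438 of 741). With no drug effect, simulation gave 70.2% (67.5% to 72.6%). These simulations drew independent noise around the fitted group means, so noise in those means counted as tumour effect. The 70.2% is therefore likely too high and the simulated ranges here too narrow, and the gap does not measure the drug alone. Toward the NT-Co level in T-TSU lay 79.0% of the 1036, with a median return of 27.7%. Simulated with no drug effect, these values were 64.9% (61.7% to 67.2%) and 9.36% (7.22% to 10.5%). Both simulated values are likely too low for the same reason, so neither gap measures the drug alone. Part of the overlap may come from the shared NT-Co arrays. Between T-Co and T-TSU, Usp2 differed by 0.25 ± 0.39, Lpin1 by -0.39 ± 0.47, St3gal5 by -0.41 ± 0.26 and Fmo2 by -0.12 ± 0.49. In T-TSU, Cyp17a1 (0.70 ± 0.49) and Hsd3b5 (-1.22 ± 0.69) were not called against NT-Co.

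Across the 15838 probe sets, the tumour and drug differences had a correlation of -0.520, where unchanged groups sharing the T-Co arrays gave -0.496 (-0.616 to -0.383). The covariance was -0.119 against -0.0604 (-0.0902 to -0.0442) simulated, a difference of -0.0584. The slope corrected for noise was -0.313. It was -0.184 without T-Co replicate 13 and -0.259 with the variance of the T-Co arrays alone, a setting chosen after seeing the data, since T-Co arrays varied more (mean variance 0.218, against 0.165 in NT-Co and 0.170 in T-TSU). Probe sets are not independent replicates.

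**Figure D3:**
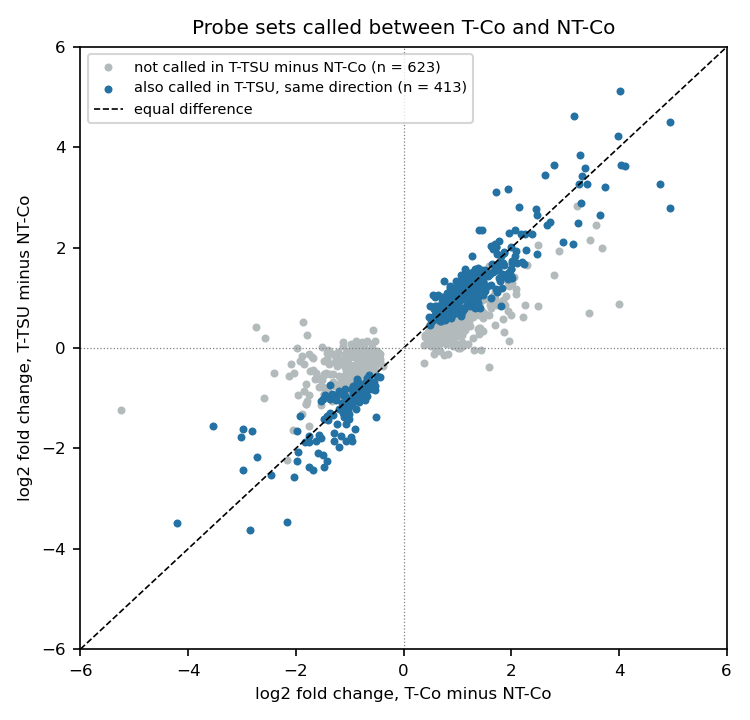
Log2 fold change of T-TSU minus NT-Co (vertical) against T-Co minus NT-Co (horizontal) for the 1036 probe sets called between T-Co and NT-Co, 1 point each. The dashed line marks equal differences, and blue points are the 413 also called in T-TSU in the same direction. Both axes share the NT-Co arrays.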

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

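The alternatives were planned, except the slope with the spread of the T-Co arrays alone, the clock index with arrays left out and the settings for calls named outside the rule, which were chosen after seeing the data. No paired analysis was possible because the groups shared fewer than 2 replicate numbers. Where the number of probe sets called moved by over 1.5 times or a call ended, the cause was not tested, apart from the smaller number of probe sets or arrays that some settings have by construction.

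For T-Co against NT-Co, 1036 probe sets were called. Without the intensity trend the count was 473, with 1 probe set per gene 586, at an adjusted p under 0.1 1816, and at an unadjusted p under 0.01 with a 2-fold difference 654. Leaving out 1 array gave 440 to 1017, with 467 without NT-Co replicate 8 and 440 without NT-Co replicate 11. For T-TSU against NT-Co (609), the count was 265 without the trend, 1026 with array weights, 335 with 1 probe set per gene and 1030 at an adjusted p under 0.1. Leaving out 1 array gave 287 to 793, with 324 and 297 without NT-Co replicates 8 and 11 and 323 and 287 without T-TSU replicates 12 and 14. The F test (902) called 312 without the trend and 523 with 1 probe set per gene. Leaving out 1 array gave 354 to 1009, with 375, 497 and 354 without NT-Co replicates 8, 10 and 11, and 573 without T-TSU replicate 14. Of the probe sets called for the tumour, 413 were also called in T-TSU, 222 with 1 probe set per gene and 200 to 438 with 1 array left out (214 and 200 without NT-Co replicates 8 and 11, 231 and 221 without T-TSU replicates 12 and 14).

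The 8 calls of T-TSU against T-Co depended on most settings. The count was 1 after quantile normalization, 25 with the 25th percentile as pseudocount, 14 with a robust trend, 5 with array weights, 24 with 1 probe set per gene, 30 at an adjusted p under 0.1 and 159 at an unadjusted p under 0.01 with a 2-fold difference. By limma it was 0 with centred arrays (1551 at an unadjusted p under 0.05), no filter (2043), no trend (1516) and only these 2 groups (1373). Leaving out 1 array gave 0 to 59. It was 0 without NT-Co replicate 8 (1551 unadjusted), NT-Co replicate 11 (1502), T-TSU replicate 2 (1190) or T-TSU replicate 14 (1356), 3 without T-Co replicate 13, 32 without T-Co replicate 10 and 59 without T-TSU replicate 12.

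Lists past the threshold numbered 11, 19 and 5 for the 3 comparisons, 0, 0 and 0 with an estimated correlation, and 7, 0 and 2 by fry. Leaving out 1 array gave 10 to 13, 12 to 18 and 4 to 7, the 12 being without T-TSU replicate 2. The cholesterol synthesis list, lower in T-TSU than in T-Co, had a mean of only -0.06 without T-Co replicate 13. It tested in the other direction there (camera adjusted p = 0.999, against 1.40e-06 to 0.0108 without 1 other array). The hepatocyte list for the tumour was lost after quantile normalization (0.0621), and the heat shock list in T-TSU against NT-Co with a filter at the 50th percentile (0.0771). For T-TSU against T-Co, the hepatocyte, complement, pancreatic and intestinal, chemokine and female-biased lists were lost under another scaling, pseudocount or filter (0.0534 to 0.743).

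Of the 19 lists that passed for T-TSU against T-Co, 11 were lost without 1 array or another, as given beside each list. They were the pancreatic and intestinal, chemokine, complement, NRF2, neutrophil, endothelial, heat shock, urea cycle, iron, stellate cell and cholesterol lists, with adjusted p from 0.0511 to 0.999.

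Of 56 gene calls that the rule named for the tumour, 38 kept their call in all settings, as did 22 of 35 in T-TSU against NT-Co and 0 of 6 for the drug. Without the intensity trend 17, 11 and 6 were lost. The genes lost without 1 array or another numbered 15 and 10 in the first 2 of these comparisons, and the 6 for the drug reached an adjusted p of 0.305 to 0.309 in the setting with the highest p. None of these calls changed sign. Of 8 calls named outside the rule for the tumour, 2 kept their call in all settings (Sparc and Srebf1), and of 2 in T-TSU against NT-Co (Clock and Met) 0 did. Without the trend the adjusted p was 0.0890 for Arntl, 0.0518 for Per3, 0.0835 for Sco2, 0.0543 for Thrsp, 0.0614 for Ghr and 0.0641 for Clock, and with only T-Co and NT-Co it was 0.0512 for Sco2. The slope between the tumour and drug differences kept its sign, at -0.406 to -0.184 with 1 array left out, the latter without T-Co replicate 13, and at -0.259 with the spread of the T-Co arrays alone. Probe sets near background, about an intensity of 36.2, could not be judged, and Mmp9 was among them, at 24.4 ± 18.4 in NT-Co.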

Other observations

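The tests of the clock genes against the acute phase response, of collection hour or feeding, and of RNA integrity, the clock index with arrays left out, and the fits of Col3a1 and Ghr with arrays left out, were chosen only after the results were seen. Lists that did not pass in any comparison held some called members in T-Co against NT-Co. Of extracellular matrix genes, 1 of 23 rose and 3 fell (2 and 6 adjusted over the list alone), among them Sparc (-0.86 ± 0.16) and Col3a1 (-1.03 ± 0.20), the latter not called without NT-Co replicate 8 (adjusted p = 0.0545). Of fatty acid and triglyceride synthesis genes, 3 of 23 rose and 2 fell (3 and 6 adjusted over the list alone), with Thrsp higher (1.40 ± 0.26) and Srebf1 lower (-1.48 ± 0.26). Of growth hormone and IGF genes, 1 of 17 rose and 1 fell (1 and 4 adjusted over the list alone), the receptor Ghr falling by 0.84 ± 0.16 and not called without NT-Co replicate 11 (adjusted p = 0.0515). Of CAR and PXR targets, 6 of 30 rose and 4 fell (7 and 9 adjusted over the list alone). Slco1a4, Abcc3 and Gstm3 are among these calls and were given above under the female-biased and NRF2 lists. Fmo2, a called female-biased gene, likewise belongs to the list of aryl hydrocarbon receptor targets given below. Of bile acid genes, 3 of 23 rose and 2 fell (6 and 4 adjusted over the list alone). Of hypoxia and glycolysis genes, 2 of 22 rose and 2 fell (2 and 2 adjusted over the list alone). Of p53 targets, 3 of 18 rose and 1 fell (3 and 1 adjusted over the list alone).

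In T-Co against NT-Co also, of cell cycle genes, 1 of 20 rose and 1 fell (1 and 4 adjusted over the list alone), of aryl hydrocarbon receptor targets, 1 of 9 rose and 1 fell (1 and 3 adjusted over the list alone), of interferon-stimulated genes, 0 of 28 rose and 1 fell (0 and 1 adjusted over the list alone), of erythroid markers, 0 of 9 rose and 1 fell (0 and 1 adjusted over the list alone), and of adipocyte markers, 1 of 6 rose and 0 fell (1 and 3 adjusted over the list alone). By limma 0 members were called in that comparison among ligands and receptors of the VEGF, PDGF, FGF and angiopoietin families (28 measured), antigen presentation genes (14), B and plasma cell markers (8), T and NK cell markers (6) and cholangiocyte markers (5). Adjusted over the list alone, 0 of these passed either, and camera gave adjusted p = 0.923, 0.714, 0.935, 0.614 and 0.495.

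In T-TSU against NT-Co, lists that did not pass held called members as well, with counts adjusted over the list alone in parentheses. Of extracellular matrix genes, 1 of 23 rose and 4 fell (1 and 6), of fatty acid and triglyceride synthesis genes, 4 of 23 rose and 0 fell (4 and 1), and of CAR and PXR targets, 3 of 30 rose and 0 fell (3 and 0). Of bile acid genes, 1 of 23 rose and 2 fell (4 and 2), of urea cycle genes, 1 of 34 rose and 3 fell (3 and 4), and of NRF2 targets, 2 of 23 rose and 2 fell (3 and 3). Of immediate early genes, 2 of 24 rose and 0 fell (2 and 1), of iron genes, 2 of 22 rose and 0 fell (3 and 0), of p53 targets, 2 of 18 rose and 0 fell (2 and 0), of growth hormone and IGF genes, 1 of 17 rose and 0 fell (1 and 0), and of hypoxia and glycolysis genes, 1 of 22 rose and 1 fell (2 and 1). Of cell cycle genes, 1 of 20 rose and 1 fell (2 and 3), of aryl hydrocarbon receptor targets, 1 of 9 rose and 0 fell (1 and 0), of interferon-stimulated genes, 0 of 28 rose and 1 fell (0 and 2), and of stellate cell markers, 0 of 20 rose and 1 fell (0 and 1).

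Clock genes were shifted in both tumour groups, by an index (10 genes of the Dbp and Per side minus Arntl, Clock and Nfil3) of 2.75 ± 1.36 in T-Co and 4.16 ± 0.50 in T-TSU (SD). The index was 1.41 ± 0.70 (SE) higher in T-TSU than in T-Co, while the acute phase list was lower. The strength of the acute phase response alone would have lowered the index. T-TSU also differed by the drug, and the hours are not given, so this index difference cannot decide that cause. T-Co replicate 13 lowered the T-Co mean, and without it the difference was 0.64 ± 0.35, the lowest with 1 array left out (highest 1.91 ± 0.84). The Arntl side lay at -1.84 ± 0.43 in T-TSU against NT-Co, as another hour of collection or feeding could give. The hours are not given in the sources used here and would be confounded with the groups. An hour or feeding difference and an effect of the tumour or its implantation therefore cannot be told apart. RNA integrity stays open too, since the beta-actin ratio was lower in both tumour groups, though that of Gapdh was 0.765, 0.765 and 0.767 in NT-Co, T-Co and T-TSU.

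The acute phase list was higher in T-Co than in NT-Co (0.89) and lower in T-TSU than in T-Co (-0.61). Without T-Co replicate 13, which had the highest value, the differences were 0.71 ± 0.13 and -0.43 ± 0.06. These SEs are over genes and do not measure the spread between arrays. The lowest T-Co array, at 0.59, lay above the highest NT-Co array (0.11), so that array was not the whole cause of the tumour difference. It lay only just above the highest T-TSU array (0.55), so the share of replicate 13 in the drug difference cannot be judged. RNA integrity would not give the drug difference, since the beta-actin ratio differed by -0.704 between T-TSU and NT-Co and by 0.038 between T-TSU and T-Co. A response to the tumour or its implantation that TSU68 lessens may be present, as a hypothesis that no test here decides. Collection hour or feeding stays open. For the tumour difference, RNA integrity alone would leave T-TSU at the level of T-Co (ratios 2.02 and 1.98), against which the -0.61 ± 0.22 (SE between arrays) argues, while RNA integrity offset by TSU68 stays open.

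Male-biased liver genes were lower in T-Co (-1.43). The lowest T-Co array had 81.1% of the NT-Co mean of the Y-linked genes measured, which argues against female animals. Without T-Co replicate 13 the difference was -1.14 ± 0.27, with an SE over genes that does not measure the spread between arrays. RNA integrity alone would leave T-TSU, with a beta-actin ratio of 2.02 against 1.98 in T-Co and 2.72 in NT-Co, at the level of T-Co, but the list was 1.05 ± 0.31 (SE between arrays) higher there, and the Gapdh ratio was 0.765 in NT-Co and in T-Co. An effect of the tumour or its implantation, RNA integrity offset by TSU68, the hour of collection and feeding stay open. So do the age and strain of the mice without tumour, which are not given separately. No test here separates these explanations.

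For 3 arrays against 3, only 10 splits exist, too few for a share under 0.05. The third group stayed in each fit, and with only T-TSU and T-Co fitted the real grouping called 0. The real split called 1036 probe sets for T-Co against NT-Co (highest other 1), 8 for T-TSU against T-Co (highest other 0) and 609 for T-TSU against NT-Co (highest other 1), so 1 of the 10 splits reached each. For the F test, 1 of 100 splits drawn of the 280 possible, the real one, gave 902, and the highest other gave 540. The split with 540 kept the NT-Co arrays together and exchanged T-Co replicate 10 with T-TSU replicate 2. All drawn splits that kept the NT-Co arrays together but mixed the tumour groups called 395 to 540. The share of 1 in 100 thus concerns any difference between the 3 groups and says little about T-Co against T-TSU.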
